A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

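The values analysed are the table of 10928 probe sets by 12 arrays that the authors deposited, on a log2 scale. Total RNA was labelled with biotin and hybridised by the Affymetrix protocol, per the labels' protocols. The submitters' processing notes name robust multi-array averaging (RMA) and the affy package, with no versions, and other steps are not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of a set, so a shift of all transcripts between groups would be removed and differences near the floor or the top of the scale are compressed. The deposited values ran from 5.42 to 14.4, and the medians of the arrays lay between 6.72 and 6.89. The depth of an array has no count, so its number limits the precision. Signal over background was judged from 1746 probe sets of fission yeast, which share the array. The 95th percentile of their means, 6.0, served as background, and 109 tested genes had a mean below it.

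Probe sets were named through a table of the array platform, which gave 1 gene symbol to 7244 probe sets, several to 1 and none to 3683. Symbols were updated through the gene identifiers of assembly R64, and 5498 probe sets matched a budding yeast gene. Of several probe sets of a gene the one with the highest mean was kept, which left 5449 genes. Among these, 114 probe sets are shared between transcripts by their name and cannot tell near-identical genes apart. Coordinates of assembly R64 were used only to find the genes next to PMA1. GAL4 was among the fixed genes, but no probe set is named for it in the tables used here.

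Groups were taken from the sample titles, with 2 arrays each. The main test fitted 1 mean per group over all 12 arrays with lmFit, contrasts.fit and eBayes of limma 3.58.1 in R 4.3.3, and adjusted p values by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The fit had 6 residual and 4.97 prior degrees of freedom, and the median residual standard deviation was 0.0841. An exact two-sided permutation test of 2 against 2 arrays cannot go below a p of 0.333, so the main test rests on the spread pooled over genes and groups. Each of the 5 groups was compared with REF, the evolved groups with each other, and the mean of the 3 evolved groups with REF, SO16 and PGM2. Where a gene was below background on every array of one side, the fold is a bound, with the dim side set to the background level where it was lower.

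The comparisons, 31 gene lists, the rule for naming genes and 17 alternatives were fixed before the data were examined. Lists were tested with the camera method of limma (cameraPR) with a preset correlation of 0.01 between genes, and adjusted over the 150 tests of 30 lists in 5 comparisons with REF, and separately over the other comparisons. The list of mitochondrially encoded genes had 0 measured members and was not tested. Camera with an estimated correlation and the rotation test fry were alternatives. Fry asks whether the genes of a list move, on balance, one way, without comparing the list with other genes. Genes are named where they had the 8 largest rises or falls against REF, or the 6 largest in another comparison, among genes past the threshold whose arrays did not overlap. The rule also takes GAL1, GAL2, GAL3, GAL4, GAL7, GAL10, GAL80, LAP3, MIG1, PGM1, PGM2, RAS2 and ERG5, and up to 4 called members of each list with the largest change, or 2 where none was called. The alternatives were other normalizations, filters on dim or shared probe sets, the mean of a gene's probe sets, other variance models, array weights, a replicate block, a fit of the compared groups alone, stricter thresholds, leaving out each array and a plain t-test. Another 4 alternatives were added after the data were seen.

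The tests were tested on simulated data with the means and spreads of the real genes. In 20 simulations of E62A against REF with 200 changed genes among 5449, 91.8% of changes of 0.5 on the log2 scale were recovered, 99.8% of changes of 1 and 99.9% of changes of 2, and 4.96% of calls were false. The simulation draws each gene independently, so it does not cover shared variation between genes. It also gives a gene the same spread in all groups, so it does not cover groups whose replicates differ more or less than others. A list shifted by 0.5 was recovered in all 20 simulations. Values expected from shared REF arrays alone came from 50 simulations of unchanged groups. Figures were drawn with matplotlib.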

Results

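Gene expression was measured on 12 Affymetrix yeast arrays, which held 6 groups of 2 arrays each. All cultures were grown in minimal medium with galactose as the carbon source, in fermenters held at pH 5.0, and were sampled in the middle of exponential growth. The labels give every sample the same strain background, CEN.PK113-7D, a haploid laboratory strain used in physiology. The group labelled REF is the reference, and the labels E62A, E62B and E62C mark 3 evolved mutants, which the study obtained by prolonged growth on galactose. The labels SO16 and PGM2 mark strains that the study engineered for faster galactose use. As known from the study, SO16 lacks GAL80, MIG1 and LAP3 (also called GAL6), and the PGM2 strain overexpresses PGM2. Levels are on the log2 scale of the robust multi-array average, and 5449 yeast genes were tested. Changes are given as log2 differences ± the standard error (SE) of the limma fit, with 2 arrays per group. The number of arrays limits the precision. The labels do not say whether the 2 arrays of a group came from separate cultures, so the adjusted p values measure only the spread between arrays, which may be technical.

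The genes that the strain names point to were examined first, as a check of the labels. On the arrays labelled SO16, GAL80, the inhibitor of the galactose activator Gal4, lay at 6.29 and 6.04, against 11.32 and 11.43 on the REF arrays. LAP3, a cysteine peptidase, lay at 5.72 and 5.87 and MIG1, a glucose repressor, at 5.84 and 5.62, all below the background level of 6.0 that was set from fission yeast probe sets. The corresponding REF levels were 10.63 and 10.77 for LAP3 and 9.20 and 9.29 for MIG1, so the label SO16 was borne out by all 3 genes. PGM2, the main phosphoglucomutase, went against the labels. It lay at 10.49 and 10.87 on the arrays labelled PGM2, below the REF values of 12.14 and 12.11, and was highest on the arrays labelled E62C, at 13.43 and 13.19. For this reason groups are named here as arrays labelled with a strain name, and any direction drawn from the labels E62C and PGM2 carries this conflict. The dots for the 6 genes plotted by label show both facts.

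**Figure D1:**
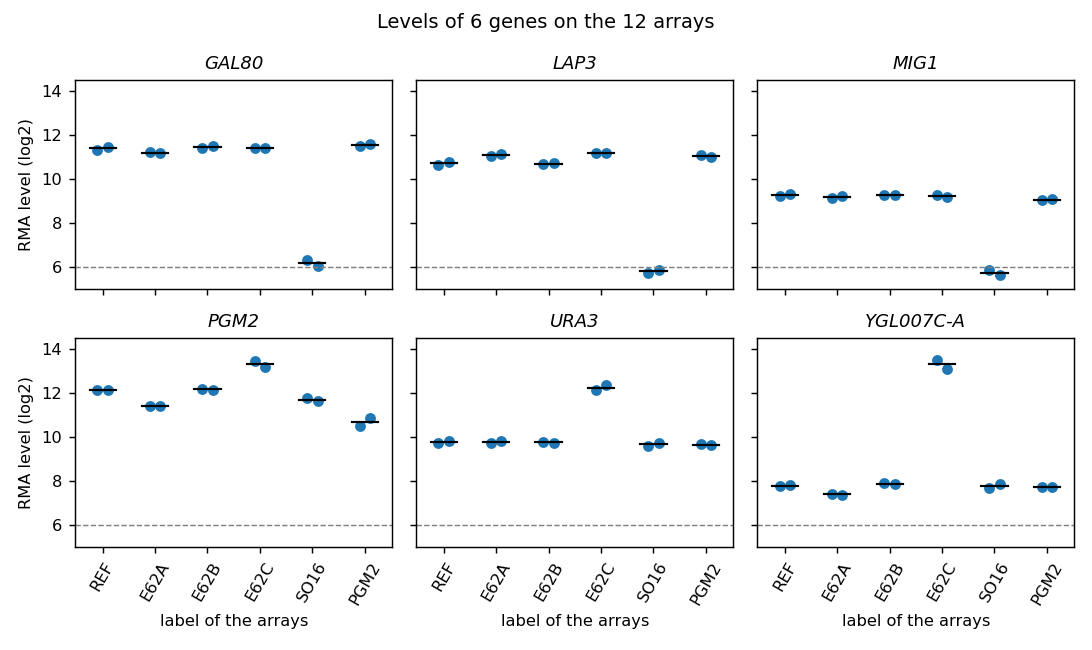
Level (log2, y axis) of 6 genes on each of the 12 arrays by label (x axis), with 1 dot per array, a bar at the mean of the 2 arrays and a dashed line at the background level of 6.0. GAL80, LAP3 and MIG1 are near background only on the arrays labelled SO16, while PGM2, URA3 and YGL007C-A are highest on the arrays labelled E62C.

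Among the galactose structural genes, GAL1 (galactokinase), GAL2 (the galactose permease), GAL7 and GAL10 lay above 13.2 on all 12 arrays, near the top of the scale, and none of the 4 passed the test in any of the 5 comparisons with REF. Their differences ranged from -0.12 ± 0.09 for GAL10 on the arrays labelled E62C to 0.10 ± 0.09 for the same gene on the arrays labelled PGM2. A change near the top of the scale can be understated. GAL3, the galactose sensor, rose by 0.49 ± 0.08 on the arrays labelled SO16 (adjusted p = 0.00236). On the same arrays PGM2 fell by 0.44 ± 0.11 (adjusted p = 0.0363), a call that ended without REF replicate 1 (adjusted p = 0.193), REF replicate 2 (0.122) or SO16 replicate 2 (0.125). PGM1, the minor phosphoglucomutase, rose by 0.31 ± 0.08 on the arrays labelled E62A, 0.47 ± 0.08 on those labelled SO16 and 0.51 ± 0.08 on those labelled PGM2. The PGM1 call for E62A ended without REF replicate 1 (adjusted p = 0.256), E62A replicate 1 (0.0622) or E62A replicate 2 (0.31), and that for SO16 without REF replicate 1 (0.0674). As a list of 8 measured genes, the pathway passed camera in none of the 5 groups, with a lowest adjusted p of 0.4. Camera looks for a shift in 1 direction, while on the arrays labelled SO16 GAL3 and PGM1 rose and PGM2 and GAL80 fell. With 4 members near the top of the scale as well, the test cannot show that the pathway was unchanged. Its median, mean and test differed in sign in 4 of these groups.

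The arrays labelled E62A differed from REF in 683 genes, of which 303 were higher and 380 lower. Genes of the general stress response, which are driven by the activators Msn2 and Msn4, were among those that fell most. Of 24 measured, 20 fell and none rose, with a median of -0.61, and adjusted over the list alone 21 fell (camera adjusted p = 2.35e-19, and 0.0131 with an estimated correlation). HSP26, a small heat shock protein, was 6.5-fold lower (-2.70 ± 0.12), and HSP12, DDR2 and GPX1 changed by -1.94 ± 0.15, -1.72 ± 0.12 and -1.71 ± 0.11. Genes of glycogen and trehalose metabolism fell as well, 13 of 19 against 1 that rose, with a median of -0.39 (adjusted p = 3.15e-10, and 0.0218 with an estimated correlation), among them GPH1, glycogen phosphorylase, at -1.06 ± 0.08. In the opposite direction, 17 of 24 ergosterol genes rose and none fell, with a median of 0.43 (19 rose adjusted over the list alone, camera adjusted p = 7.66e-13, and 0.0122 with an estimated correlation). ERG3 rose by 1.07 ± 0.08, ERG28 by 0.87 ± 0.09 and ERG5, one of the genes fixed in advance, by 0.45 ± 0.10. Of 35 Gcn4 targets of amino acid synthesis, 15 rose, including ARG1 by 0.78 ± 0.08. This list had a camera adjusted p of 3.90e-13, and an adjusted p = 0.145 with an estimated correlation.

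The largest single rises on the arrays labelled E62A were those of ATF2, an alcohol acetyltransferase, by 1.64 ± 0.07, MEP2, an ammonium permease, by 1.62 ± 0.13, and OPT2 by 1.58 ± 0.11. EGO4 (-2.86 ± 0.17), HXT17 (-2.78 ± 0.18), SIP18 (-2.70 ± 0.15) and STL1, a glycerol transporter (-2.04 ± 0.14), fell most beside HSP26, and the HXT17 probe set is shared with near-identical genes. All 7 measured genes specific to mating type a fell, MFA1 at -1.65 ± 0.14, and FUS1, a mating gene, changed by -2.03 ± 0.08 (list adjusted p = 1.11e-09, and 0.011 with an estimated correlation). Of the 4 measured genes specific to mating type alpha, 2 fell as well, MF(ALPHA)1 at -1.71 ± 0.14 and STE3 at -1.24 ± 0.14, though that list did not pass (adjusted p = 0.0542, and adjusted p = 0.342 with an estimated correlation). Cell wall genes fell in 7 of 18 cases (adjusted p = 5.61e-05, and 0.0209 with an estimated correlation), and subunits of the respiratory chain and ATP synthase in 6 of 36 (median -0.13, adjusted p = 4.43e-05, and 0.0469 with an estimated correlation). In the pentose phosphate list the 4 genes that fell were the minor isoforms SOL4 (-1.46 ± 0.11), GND2 (-1.47 ± 0.11), TKL2 (-1.75 ± 0.15) and NQM1 (-1.22 ± 0.09). In the same list 1 member rose, and the median of the list was -0.06 (adjusted p = 0.0237, and adjusted p = 0.316 with an estimated correlation). PGM2 (-0.72 ± 0.11) and RAS2, a regulator of the cyclic AMP pathway (-0.28 ± 0.06), fell. RAS2 did not pass without E62A replicate 1 (adjusted p = 0.131), REF replicate 1 (0.0647) or REF replicate 2 (0.0543), nor ERG5 without REF replicate 1 (0.0989), E62A replicate 1 (0.0713) or E62A replicate 2 (0.0821). The count of changed genes was 302 without E62A replicate 1, 315 without E62A replicate 2, 364 without REF replicate 1 and 413 without REF replicate 2, and it was 1113 when only these 4 arrays were fitted.

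The arrays labelled E62B did not differ from REF in any named gene by limma at an adjusted p under 0.05. The smallest adjusted p was 0.111, and 97 genes had an unadjusted p under 0.05. The plain t-test with Benjamini-Hochberg adjustment also called 0 genes, with 212 at an unadjusted p under 0.05. It called 0 for E62C and SO16 too, so its 0 says little about E62B. Fitting only these 4 arrays gave 4 genes, and array weights gave 2. A replicate block for each of 2 sets of groups, chosen after seeing the data from the residuals of these arrays, gave 5, SFC1 and IDP2 among them. With all probe sets tested, 2 passed, and neither had a gene name. They were higher on the arrays labelled E62B by 1.23 ± 0.06 (adjusted p = 3.43e-05) and 1.22 ± 0.08 (adjusted p = 6.29e-04), and their mean levels were also above those of REF on the arrays labelled E62C, SO16 and PGM2. Among the genes that the fixed rule names for this comparison, the largest differences were those of FIT3 (-1.75 ± 1.2) and FIT2 (-1.51 ± 1.30), iron-related cell wall proteins that varied widely between replicates. Next came SFC1 (-0.66 ± 0.13) and IDP2 (-0.47 ± 0.08), both on the Cat8 and Adr1 list. The stress genes SPI1 and CTT1 lay at 0.46 ± 0.11 and 0.35 ± 0.11. The fixed galactose genes lay within -0.06 (GAL10) and 0.07 (GAL80) of REF, and PGM2 at 0.03 ± 0.11. As a list, 18 Cat8 and Adr1 targets of gluconeogenesis and the glyoxylate cycle shifted down with a median of -0.20, although no member passed alone and 2 did adjusted over the list alone (camera adjusted p = 6.65e-17, and 2.30e-04 with an estimated correlation). Chaperones driven by Hsf1 shifted by -0.06 (adjusted p = 9.50e-06, and 0.0329 with an estimated correlation). Camera sets a list against the spread of all genes in the same comparison. That spread was narrow for E62B, where the 97 genes at an unadjusted p under 0.05 are fewer than chance gives. Small shifts can therefore pass here, with either correlation, and a low p does not mean a large shift. The stress list lay slightly above REF, with a median of 0.08 (adjusted p = 1.14e-04, and adjusted p = 0.405 with an estimated correlation), and the reserve carbohydrate list at 0.05 (adjusted p = 0.00144, and adjusted p = 0.32 with an estimated correlation). The iron list had a median of -0.29 (adjusted p = 4.65e-04, and adjusted p = 0.549 with an estimated correlation), but without REF replicate 1 its median was -0.0036 and without E62B replicate 2 its adjusted p was 0.0915. The stress call for E62B ended without E62B replicate 1 (adjusted p = 0.123).

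Arrays were also compared over all genes. The standard deviation of the log2 difference between a REF and an E62B array was 0.0944 to 0.170 over the 4 such pairs. The replicate pair of REF had 0.139 and that of E62B 0.0989, so that 2 of the 4 lay below both and 1 above both. The 2 low pairs both hold REF replicate 2 (0.0969 and 0.0944). Those with REF replicate 1 had 0.128 and 0.170, so the 4 pairs are not independent. Replicate pairs of the 6 groups spanned 0.0919 to 0.210, the highest being that of E62C, which holds an array with weak hybridisation controls, and the other 56 pairs of arrays from different groups spanned 0.229 to 0.364.

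**Figure D2:**
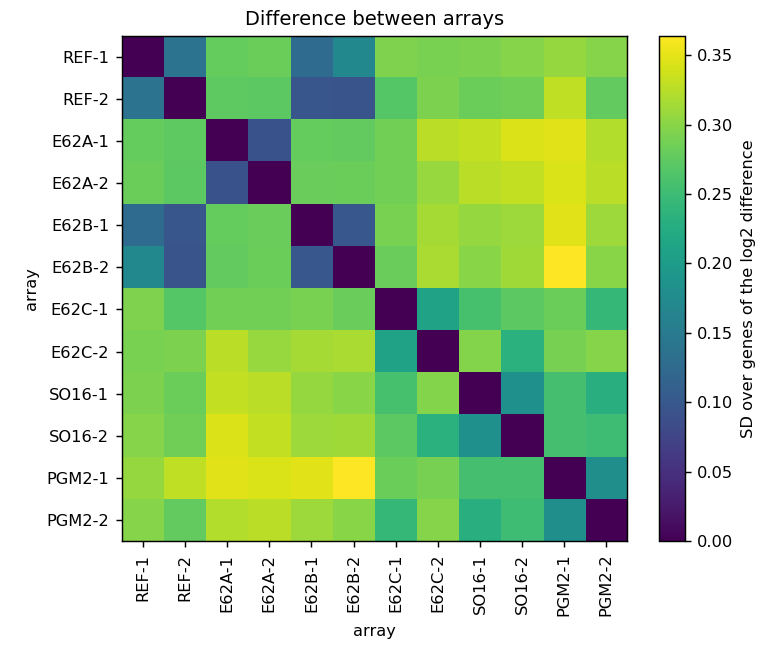
Standard deviation over 5449 genes of the log2 difference between each pair of the 12 arrays, as colour, with the arrays by label and replicate on both axes. The 4 cells that pair REF with E62B arrays, from 0.0944 to 0.170, lie within the range of replicate pairs, 0.0919 to 0.210, and the highest lies above the replicate pairs of REF (0.139) and E62B (0.0989).

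The arrays labelled E62C differed from REF in 534 genes, with 264 higher and 270 lower. The stress list fell in 20 of 24 members with a median of -0.92 (22 fell adjusted over the list alone, camera adjusted p = 1.75e-30, and 0.00154 with an estimated correlation), with HSP26 at -2.49 ± 0.12, DDR2 at -2.31 ± 0.12 and HSP12 at -1.98 ± 0.15. Reserve carbohydrate genes fell in 16 of 19 cases with a median of -0.69 (adjusted p = 1.43e-21, and 3.69e-04 with an estimated correlation), among them GLC3, the glycogen branching enzyme, at -1.20 ± 0.08 and TSL1 of the trehalose synthase complex at -1.40 ± 0.12. Of 35 amino acid synthesis genes 18 rose (adjusted p = 3.47e-09, and adjusted p = 0.256 with an estimated correlation), as did 14 of 79 ribosome biogenesis genes (median 0.24, 34 adjusted over the list alone, adjusted p = 2.24e-11, and adjusted p = 0.296 with an estimated correlation). Sulfate and methionine genes rose in 8 of 22 cases, MUP1 by 0.49 ± 0.08 (adjusted p = 1.14e-04, and adjusted p = 0.155 with an estimated correlation). The cell wall list fell, CWP1 at -1.54 ± 0.15 and SED1 at -0.95 ± 0.07 (adjusted p = 5.86e-08, and 0.00156 with an estimated correlation).

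YGL007C-A, a short reading frame that neighbours the plasma membrane proton pump gene PMA1 in assembly R64, rose by 5.51 ± 0.11, or 45.6-fold. PMA1 itself, looked up after its neighbour's value was seen, changed by -0.42 ± 0.08 (adjusted p = 0.00523). URA3, a pyrimidine synthesis gene used as a selection marker, rose by 2.47 ± 0.08 and URA1 of the same pathway by 1.14 ± 0.10. PHO5, an acid phosphatase, was below background on both REF arrays and at least 3.45-fold higher on the arrays labelled E62C (adjusted p = 4.12e-08). PGM2 rose by 1.18 ± 0.11 (adjusted p = 5.92e-05). The label of an evolved mutant does not rule out such a rise, and the conflict lies in the lower PGM2 level on the arrays labelled PGM2. RAS2 fell by 0.43 ± 0.06 and LAP3 rose by 0.49 ± 0.08. E62C replicate 2 had weak hybridisation controls and strong ribosomal RNA signal, described with the arrays labelled SO16. Without REF replicate 1 the count of changed genes was 250, and with only these 4 arrays in the fit it was 316.

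The arrays labelled SO16 differed from REF in 479 genes, 201 higher and 278 lower. GAL80, LAP3 and MIG1 led the list, GAL80 with -5.21 ± 0.08 and, against a level below background, LAP3 with at least a 25.9-fold and MIG1 with at least a 9.45-fold lower level. Of the 4 other Gal4 targets 3 rose, PCL10 by 0.78 ± 0.08, MTH1 by 0.53 ± 0.07 and GCY1 by 0.29 ± 0.06 (camera adjusted p = 7.26e-05, and 0.00239 with an estimated correlation). SUC2, invertase, a gene repressed through Mig1, rose by 0.67 ± 0.12, and ADR1 by 0.57 ± 0.09. Without REF replicate 1 neither SUC2 (adjusted p = 0.0528) nor GCY1 (0.118) passed, and GCY1 did not without SO16 replicate 1 (0.0568). The Cat8 and Adr1 list as a whole had 5 members higher and 2 lower (median 0.13, adjusted p = 0.038, and adjusted p = 0.465 with an estimated correlation). Its call ended without REF replicate 2 (adjusted p = 0.0567) or SO16 replicate 1 (0.179). The stress list fell in 17 of 24 members with a median of -0.71 (adjusted p = 4.02e-24, and 0.00385 with an estimated correlation), and the reserve carbohydrate list in 15 of 19 with a median of -0.64 (adjusted p = 6.79e-17, and 0.00156 with an estimated correlation). The amino acid permease genes BAP3 and AGP1 rose by 1.98 ± 0.18 and 1.52 ± 0.14, PRM5 by 1.72 ± 0.10 and the phosphate transporter gene PHO84 by 1.37 ± 0.17. HSP26 (-2.73 ± 0.12), SIP18 (-2.95 ± 0.15) and FMP16 (-2.24 ± 0.08) fell most after MIG1.

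On SO16 replicate 2 and E62C replicate 2, the E. coli hybridisation controls averaged 8.91, against 10.7 on the other 10 arrays, and the ribosomal RNA probe sets averaged 11.7, against 9.65. Without both arrays, an alternative chosen after seeing the data, 897 genes differed between the arrays labelled SO16 and REF, and the stress list had a median of -0.80. The same alternative gave 744 genes for the arrays labelled E62C, with a stress median of -1.07. For the arrays labelled SO16 the count was 228 without REF replicate 1, 253 with array weights and 271 with only these 4 arrays in the fit.

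The arrays labelled PGM2 differed from REF in 739 genes, with 383 higher and 356 lower. PGM2 itself fell by 1.45 ± 0.11 (adjusted p = 1.02e-05), against the label. Genes induced through Cat8 and Adr1 rose in 13 of 18 cases and none fell, with a median of 0.58 (camera adjusted p = 3.15e-10, and 0.00385 with an estimated correlation). Among them SFC1, a mitochondrial succinate and fumarate carrier, rose by 1.54 ± 0.13, MLS1, malate synthase, by 1.14 ± 0.11, ICL1, isocitrate lyase, by 1.07 ± 0.10 and ADH2 by 1.00 ± 0.09. The stress list fell in 21 of 24 members with a median of -0.93 (adjusted p = 1.14e-25, and 0.00289 with an estimated correlation), HSP26 at -3.45 ± 0.12 and MSC1 at -2.19 ± 0.10. Reserve carbohydrate genes fell in 14 of 19 cases with a median of -0.87 (adjusted p = 1.36e-17, and 0.00154 with an estimated correlation), GPH1 at -1.68 ± 0.08. Cell wall genes went both ways, with 7 higher, such as GSC2, a glucan synthase gene, by 1.10 ± 0.11, and 2 lower, such as CWP1 at -1.20 ± 0.15 (adjusted p = 6.04e-04, and adjusted p = 0.0631 with an estimated correlation).

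Histone genes fell in 6 of 9 cases on the arrays labelled PGM2, with HTA1 at -0.54 ± 0.09 (median -0.42, adjusted p = 1.65e-06, and adjusted p = 0.155 with an estimated correlation). The Ras and protein kinase A list had 4 lower members, RAS2 (-0.52 ± 0.06), TPK2 (-0.60 ± 0.11), CYR1 (-0.49 ± 0.10) and YAK1 (-0.37 ± 0.08), and none higher (adjusted p = 0.00735, and adjusted p = 0.246 with an estimated correlation). CYR1 did not pass without REF replicate 1 (adjusted p = 0.0569), nor YAK1 without REF replicate 2 (0.0908) or PGM2 replicate 1 (0.105). The largest rises were PRM5 by 2.39 ± 0.10 and PHO89, a phosphate transporter, by 1.57 ± 0.12. CYC7, an isoform of cytochrome c (-1.92 ± 0.16), and HXT17, with its shared probe set (-2.87 ± 0.18), fell. The count was 358 without PGM2 replicate 1, 436 without REF replicate 1 and 425 without REF replicate 2.

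**Figure D3:**
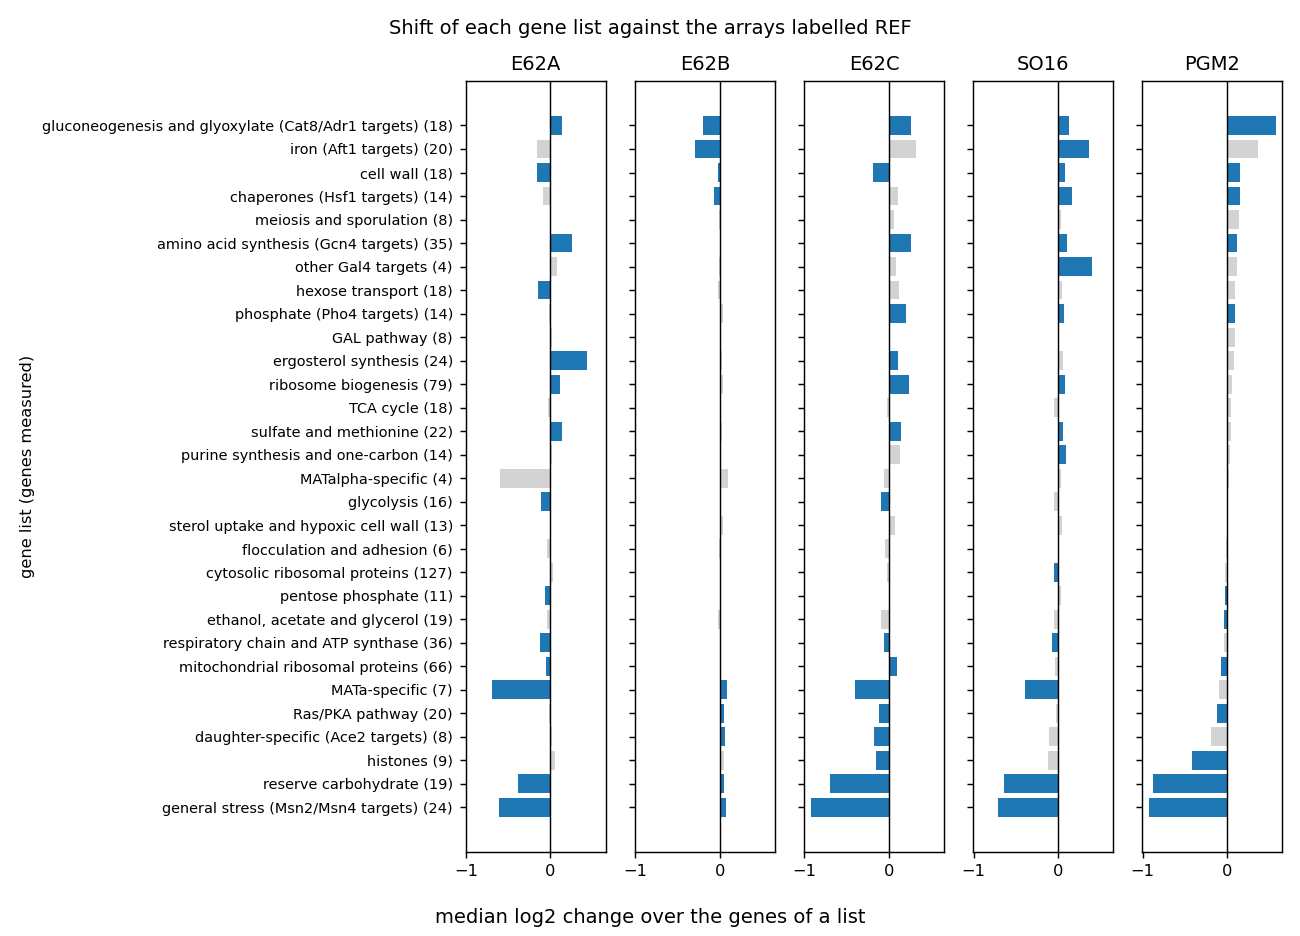
Median log2 change against REF (x axis) of each of 30 gene lists (y axis, with the number of genes measured), 1 panel per label. Blue bars passed the camera test with a preset correlation at an adjusted p under 0.05 and grey bars did not. The stress list has medians of -0.61, -0.92, -0.71 and -0.93 for the labels E62A, E62C, SO16 and PGM2, and 0.08 for E62B.

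The mean of the 3 evolved groups against REF is an average that 1 group can drive, so a call in it need not be shared by all 3. It includes the arrays labelled E62B, which held no called gene, and those labelled E62C, whose PGM2 level lay above that of the arrays labelled PGM2. The mean differed from REF in 198 genes, 67 higher and 131 lower. No gene passed in the same direction in each of the 3 comparisons with REF by limma, which follows from the count of 0 for E62B. The count by chance in simulated unchanged groups sharing the REF arrays was also 0, which is so for any unchanged groups with few calls. The observed count was 0 under each alternative run. Among genes whose levels on all 6 evolved arrays lay beyond both REF arrays, the largest rises in the mean were OPT2 (0.93 ± 0.09), PLB2 (0.74 ± 0.07) and ATF2 (0.62 ± 0.06), and the largest falls STL1 (-0.85 ± 0.12), DDR48 (-0.73 ± 0.08) and PRR2 (-0.68 ± 0.05). For ATF2 and STL1 most of the change in the mean came from the arrays labelled E62A. ERG5 (0.16 ± 0.08) and PGM2 (0.16 ± 0.09) did not pass. The stress list fell in 15 of 24 members (median -0.55, adjusted p = 2.01e-31, and 7.52e-04 with an estimated correlation). This fall came from the arrays labelled E62A and E62C, with medians of -0.61 and -0.92 against REF, while that for E62B was 0.08. With the mean taken without the arrays labelled E62B, an alternative chosen after seeing the data, 543 genes differed. The count was 81 without REF replicate 1, 85 without REF replicate 2, 127 without E62B replicate 2 and 471 without the 2 arrays with weak hybridisation controls.

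The 3 evolved groups were also compared with each other. Against the arrays labelled E62A, those labelled E62B differed in 676 genes, 398 higher and 278 lower. Stress genes were higher on the E62B arrays in 20 of 24 cases (median 0.75, adjusted p = 5.70e-21, and 0.0111 with an estimated correlation), with HSP26 at 2.79 ± 0.12. Ergosterol genes were lower in 14 of 24 (median -0.34, adjusted p = 1.10e-12, and 0.0121 with an estimated correlation), and all 7 genes specific to mating type a were higher. The arrays labelled E62C differed from those labelled E62A in 970 genes, 543 higher and 427 lower. YGL007C-A (5.91 ± 0.11), URA3 (2.46 ± 0.08), PRM5 (2.14 ± 0.10) and PGM2 (1.91 ± 0.11) were higher, and HPF1 (-2.49 ± 0.20), BDH2 (-1.52 ± 0.12) and ATF2 (-1.47 ± 0.07) lower. Of the ergosterol genes 10 of 24 were lower on the E62C arrays and 1 higher (adjusted p = 3.02e-06, and adjusted p = 0.142 with an estimated correlation), and ERG5 changed by -0.52 ± 0.10. The arrays labelled E62C differed from those labelled E62B in 657 genes, 298 higher and 359 lower, with HSP26 at -2.58 ± 0.12 and PGM2 at 1.15 ± 0.11. Cat8 and Adr1 targets were higher in 12 of 18 (adjusted p = 9.53e-09, and 0.0111 with an estimated correlation). Leaving out any 1 array gave 314 to 341 genes for E62B against E62A. The count for E62C against E62A was 375 without E62A replicate 1, 408 without E62A replicate 2 and 622 without E62C replicate 2. The count for E62C against E62B was 284 without E62B replicate 1 and 322 without E62B replicate 2.

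Set against the engineered groups, the evolved mean differed from the arrays labelled SO16 in 569 genes, 317 higher and 252 lower. LAP3, GAL80 (5.18 ± 0.07) and MIG1 led, and HXT7 (1.74 ± 0.14), whose probe set is shared, and MEP2 (1.59 ± 0.11) were also higher. PRM5 (-2.33 ± 0.08), BAP3 (-1.85 ± 0.15) and AGP1 (-1.24 ± 0.11) were lower in the evolved mean. Cell wall genes were lower in 8 of 18 and none was higher (adjusted p = 1.79e-10, and 4.06e-04 with an estimated correlation). The other Gal4 targets were lower in 3 of 4 (adjusted p = 9.87e-05, and 0.00384 with an estimated correlation). Against the arrays labelled PGM2, the evolved mean differed in 1009 genes, 517 higher and 492 lower. Cat8 and Adr1 targets were lower in the evolved mean in 13 of 18 (median -0.53, adjusted p = 2.83e-09, and 0.0103 with an estimated correlation) and histone genes higher in 8 of 9 (adjusted p = 3.02e-06, and adjusted p = 0.142 with an estimated correlation). PGM2 was higher in the evolved mean by 1.61 ± 0.09, a direction that goes against the labels. Without the 2 arrays with weak hybridisation controls the counts were 1067 against SO16 and 1528 against PGM2. Without E62A replicate 1 or E62B replicate 1 the count against SO16 was 376, with array weights it was 235 and without the arrays labelled E62C it was 877. Against PGM2 it was 446 without PGM2 replicate 1.

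Fold changes against REF were compared between groups over the 5449 genes, which are not independent replicates. Unchanged groups that share the REF arrays gave a simulated Pearson correlation near 0.50 and a covariance near 0.0052. The correlation of 0.50 applies only where both groups are unchanged, since real changes widen the spread of the fold changes. For changed groups only the covariance can be set beside its simulated value. The arrays labelled SO16 and PGM2 had a correlation of 0.70 (Spearman 0.61) and a covariance of 0.0520, E62C and SO16 0.62 (Spearman 0.64, covariance 0.0427) and E62C and PGM2 0.60 (Spearman 0.45, covariance 0.0431). The E62A group gave lower values, 0.42 with E62C (covariance 0.0287), 0.31 with PGM2 (covariance 0.0230) and 0.28 with SO16 (covariance 0.0197). These covariances were still above that of unchanged groups. Correlations for E62B ran from -0.23 with PGM2 (covariance -0.0061) to 0.09 with E62A (covariance 0.00225), and all 4 of its covariances were below that of unchanged groups. SO16 and PGM2 shared 139 genes higher and 199 lower, where independent lists would share 14.1 and 18.2, and 7 genes went opposite ways. E62C shared 68 higher and 182 lower with SO16 (independent lists 9.74 and 13.8, 11 opposite) and 91 and 192 with PGM2 (18.6 and 17.6, 18 opposite). E62A shared 83 and 118 with E62C (14.7 and 18.8, 29 opposite), 38 and 107 with SO16 (11.2 and 19.4, 61 opposite) and 67 and 122 with PGM2 (21.3 and 24.8, 85 opposite). Part of each overlap may come from the shared REF arrays, since 2 arrays are too few to give each comparison its own.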

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

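All tests in this part were chosen after the results were seen, except the planned comparisons between the evolved groups and the planned fits without 1 array. The changes of the 3 evolved groups against REF differed from each other by a direct test. E62B against E62A gave 676 genes, E62C against E62A 970 and E62C against E62B 657. Signals were also seen outside the main comparisons. The array carries 47 probe sets for reporter sequences that are not named here. The tables used here give them no gene name, only the code of a source sequence, which was not looked up. Whether any belongs to a yeast gene or a construct was not established, so the meaning of their values is open. A set of 6 of them was above REF in each of 4 groups, with medians of 3.64 for the label E62A, 4.39 for E62C, 3.79 for SO16 and 4.49 for PGM2, and the 6 were picked for that pattern. Most of the 6 share the same source code, so they stand for fewer sequences than 6. On the REF and E62B arrays all 6 lay between 5.42 and 6.33. Another reporter probe set was higher than REF by 7.79 on the arrays labelled SO16. One with the same source code was higher by 1.78 on those labelled E62C (8.64 and 7.19, against 6.15 and 6.11 on REF). These 2 did not move together, as the first lay at -0.04 on E62C and the second at 0.07 on SO16. A further one, with another code, was higher by 0.69 on the arrays labelled SO16 and by 0.50 on those labelled E62C. With all probe sets tested, 2 without a gene name were higher on the arrays labelled E62B than on REF, by 1.23 and 1.22. Their mean levels were 6.68 and 7.52 on REF and 6.73 and 7.55 on E62A, but 7.91 and 8.74 on E62B, 7.40 and 8.19 on E62C, 7.98 and 8.73 on SO16 and 7.25 and 8.06 on PGM2, so that here E62B lay with the latter groups and not with REF. The 3 control probe sets for URA3, on average, were higher by 2.44 on the arrays labelled E62C.

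The first pattern is that no named gene passed the planned test between the arrays labelled E62B and REF. Even so, 2 probe sets passed and, with an estimated correlation, 2 gene lists. The shifts of these lists were small but were set against a narrow spread. With a replicate block for each of 2 sets of groups that were found in the residuals, 5 named genes passed as well. Too few arrays to see changes of the size found elsewhere is argued against by the other 4 groups, which gave at least 479 genes with as many arrays. That the arrays labelled E62B hold RNA of the reference strain is a candidate explanation. Of the 4 pairs of a REF and an E62B array, 2 differed less than the replicate pairs of both groups (standard deviations of 0.139 and 0.0989). The pair that differed most, at 0.170, exceeded both. As the 2 low pairs hold REF replicate 2 and the highest holds REF replicate 1, this split follows the REF array and decides little. Against reference RNA stand the 2 probe sets without a gene name that differed by 1.23 and 1.22, which identical RNA would not give. They lay high in 3 of the other 4 groups as well. On the other side, the 6 shared reporter probe sets had a median difference from REF of -0.07 on the arrays labelled E62B. The lowest such median in the other 4 groups was 3.64. They were picked for lying above REF in those 4 groups, not for staying low in E62B. An evolved strain with few transcript changes cannot be told apart from reference RNA of another culture or stock, because these values leave both open. The 97 genes at an unadjusted p under 0.05 are fewer than the 272 that chance alone gives. The spread was pooled with groups such as E62C, whose replicates differed more, which can lower this number. The plain t-test, which does not pool, gave 212.

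The second pattern is the level of PGM2, which was high on the arrays labelled E62C with URA3 and YGL007C-A, and low on those labelled PGM2. That PGM2 simply moved with the stress genes is argued against for the arrays labelled E62C, where the stress list fell with a median of -0.92. For those labelled PGM2 it remains possible, as PGM2 changed by -1.45, within the range of that list. The list ran there from -3.45 to 0.20, so wide a range that this check could hardly exclude the explanation. The weak hybridisation controls of E62C replicate 2 are argued against as the source, because without that array PGM2 was still higher than REF by 1.31. An exchange of labels between these groups may account for both parts of the pattern. PGM2 differed by 2.63 between them in the direction opposite to the labels. That value is the pattern itself, so it is no test of an exchange. Whether the arrays labelled PGM2 hold an evolved strain, and whether the URA3 and YGL007C-A signal comes from an engineered construct, of which the labels say nothing, was not tested, and a wrong label on a single group also stays open.

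The third pattern is the fall of stress and reserve carbohydrate genes in 4 of the 5 groups. High values on the REF arrays by chance would have to be shared by the arrays labelled E62B, against which the stress medians were -0.75 or lower in all 4 groups. Those arrays may hold reference RNA, and same-numbered REF and E62B arrays deviated together (correlation 0.47). They are therefore not a sure independent control, and this comparison does not decide the question. The arrays with weak hybridisation controls are argued against as the source, since the groups without such an array had medians of -0.61 or lower. Evolution or engineering for faster galactose use is the difference the design names, and it stays open, untested, though by the labels it covers E62B too, where the stress median was 0.08. A strain history shared by the 4 groups could also be at work, since each carried the reporter signal, with a lowest median of 3.64 against -0.07 for E62B. The reporters were picked for lying above REF in these 4 groups, so these values do not decide it.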

How the results depend on the processing

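Alternatives without the 2 arrays with weak hybridisation controls, evolved means without a group and a block for each of 2 sets of groups were chosen after the data were seen, and the others were fixed before. Quantile normalization over yeast genes, median centring, leaving out dim genes or shared probe sets, averaging probe sets and a variance trend kept each count of changed genes within 1.5 times its value. Median centring moved the median of all genes by under 0.1 in each comparison. Testing all probe sets gave 2 calls for E62B against REF, both probe sets without a gene name. With the replicate number as a block, the counts were 794, 0, 632, 535 and 818 for E62A, E62B, E62C, SO16 and PGM2, none moved by over 1.5 times. Same-numbered arrays deviated together in some groups and not in others, with correlations from -0.35 to 0.54 over 15 pairs of groups, 6 of them over 0.1. These were REF with E62B (0.47) and PGM2 (0.53), E62B with PGM2 (0.52), E62C with SO16 (0.54), and E62A with E62C (0.31) and SO16 (0.18). These 6 were all pairs within 2 sets, 1 of REF, E62B and PGM2 and 1 of E62A, E62C and SO16, while the 9 pairs between the sets ran from -0.35 to 0.10. The labels name no such sets. E62C and SO16, the pair with the highest correlation, are also the groups whose replicate 2 had weak hybridisation controls and strong ribosomal RNA signal. Whether this gave their correlation was not tested. As not every pair was over 0.1 and the labels give the numbers no meaning, the numbers were not taken to pair the arrays. A replicate block with its own term in each set gave 947, 5, 856, 662 and 994 genes in the order above, with 314 for the evolved mean and 997 for E62C against E62B. The 5 for E62B were PRM5 (-0.69), IDP2 (-0.47), SFC1 (-0.66), AAD3 (-0.48) and FRE7 (1.15), so its count of 0 depends on the model of the spread. The sets were found in the residuals of the same arrays, so this block lowers the residual spread by construction. It kept 65 of the 66 list shifts and ended that of the genes specific to mating type a for E62B (adjusted p = 0.067).

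Stricter thresholds lowered the counts by construction. At an adjusted p under 0.01 they were 352 (E62A), 265 (E62C), 261 (SO16), 379 (PGM2), 109 (evolved mean), 374 (E62B against E62A), 440 (E62C against E62A), 332 (E62C against E62B), 285 (evolved mean against SO16) and 567 (evolved mean against PGM2). With a change of at least 2-fold added to the 0.05 threshold they were, in that order, 63, 47, 45, 62, 12, 74, 57, 62, 34 and 45. The plain t-test, with few degrees of freedom, gave 4, 0, 0 and 1 genes for E62A, E62C, SO16 and PGM2. Array weights gave 1224 for E62A, 2 for E62B, 253 for SO16, 1950 for E62B against E62A and 235 for the evolved mean against SO16. Fitting only the groups compared gave 1113 for E62A, 4 for E62B, 316 for E62C, 271 for SO16 and 1823 for E62B against E62A. In both, groups with close replicates gained calls. Without the 2 arrays with weak hybridisation controls the counts were 897 for SO16, 471 for the evolved mean, 1067 for it against SO16 and 1528 for it against PGM2. The evolved mean gave 543 genes against REF without the arrays labelled E62B and, without those labelled E62C, 877 against SO16. The cause of the gains was not tested.

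Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 302 to 413 genes for E62A, 0 to 0 for E62B, 250 to 551 for E62C, 228 to 536 for SO16, 358 to 549 for PGM2 and 81 to 242 for the evolved mean. Between groups it gave 314 to 341 for E62B against E62A, 375 to 1010 for E62C against E62A, 284 to 736 for E62C against E62B, 376 to 715 for the evolved mean against SO16 and 446 to 1109 for it against PGM2. List shifts numbered 66, and 60 to 75 without 1 REF array. With an estimated correlation 17 of the 66 held, and fry called 48 lists, 40 of them among the 66. The 17 were stress and reserve carbohydrate genes in the 4 groups other than E62B, Cat8 and Adr1 targets for E62B and PGM2, cell wall genes for E62A and E62C, ergosterol, respiratory chain and mating type a genes for E62A, chaperones for E62B and other Gal4 targets for SO16.

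Results that turned their direction were few. The iron list for E62B had medians from -0.575 to -0.00363 when 1 array was left out, and the ribosomal protein list for SO16 from -0.0672 to -0.0159, which it also had without the 2 arrays with weak hybridisation controls. In both the direction of the test turned, not that of the median. Without the arrays labelled E62B, GND2 (-0.000826), CIT3 (0.0265) and GPH1 (-0.0179) turned in the evolved mean against SO16, and without those labelled E62C, PHO5 (-0.0714) turned in it against PGM2. The cause was not tested. Background at 6.0 limits what is seen of weak transcripts, and the top of the scale what is seen of the galactose genes.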

Other observations

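The set of 4 groups other than E62B was chosen after the data were seen. In it, 85 genes fell and 24 rose in all 4 comparisons with REF, where independent lists would give 0.0628 and 0.0381. Simulated unchanged groups that share the REF arrays gave 0 such genes, but unchanged groups give few calls, so this 0 says little about the 85 and 24. Part of the overlap may come from the shared REF arrays. Of the 85, 16 belonged to the 24 stress genes and 12 to the 19 reserve carbohydrate genes, which is no further evidence on these lists, since the groups were chosen after their falls were seen. HSP26, SIP18, DDR2 and HSP12 had the largest mean falls, at -2.84, -2.67, -2.11 and -2.07. RAS2 was among the 85 as well, and so were GND2 and SOL4 of the pentose phosphate pathway. Of the 24, 3 were Cat8 and Adr1 targets and 3 Gcn4 targets. The Gcn4 targets, ARG1, ASN1 and ASN2, were no longer called for SO16 without REF replicate 1 or without SO16 replicate 2. Membership of the 24 therefore rests on single arrays for these genes. OPT2, SFC1 and ARO9, an aromatic aminotransferase, rose most, with means of 1.06, 1.00 and 0.93.

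Other lists moved as well. Hexose transport genes fell in 5 of 18 cases on the arrays labelled E62A (adjusted p = 0.00771, and adjusted p = 0.24 with an estimated correlation), HXT5 at -0.98 ± 0.13. Glycolytic genes fell there in 4 of 16 cases, among them TDH1 (-1.18 ± 0.11) and ENO1 (-0.75 ± 0.07), with an adjusted p of 0.00119, and adjusted p = 0.303 with an estimated correlation. On the arrays labelled E62C, phosphate genes rose in 3 of 14 cases (adjusted p = 2.61e-04, and adjusted p = 0.32 with an estimated correlation), and genes specific to mating type a fell in 4 of 7 (adjusted p = 2.18e-05, and adjusted p = 0.12 with an estimated correlation). Purine and one-carbon genes shifted up on the arrays labelled SO16 (median 0.09, adjusted p = 0.0143, and adjusted p = 0.534 with an estimated correlation). Chaperones shifted up on the arrays labelled SO16 and PGM2, with medians of 0.16 and 0.15 (adjusted p = 0.00274 and 0.00918, and adjusted p = 0.232 and 0.287 with an estimated correlation), though for PGM2 not without PGM2 replicate 2 (adjusted p = 0.0607). The ethanol, acetate and glycerol list shifted down on those labelled PGM2 in 6 of 19 genes (adjusted p = 0.0243, and adjusted p = 0.256 with an estimated correlation), but not without REF replicate 2 (adjusted p = 0.0683) or PGM2 replicate 1 (0.0663). The 6 lists that passed in no group were the GAL pathway, the TCA cycle, sterol uptake and hypoxic cell wall, flocculation, genes specific to mating type alpha, and meiosis. Of 403 probe sets above background with no gene name, 48 differed from REF for E62A, 2 for E62B, 44 for E62C, 38 for SO16 and 47 for PGM2.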
